A study of Mus musculus with 18 samples.

How the data were processed

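RNA from 3 glands of orchiectomised male mice given placebo or testosterone pellets for 21 days was measured on 18 1-colour arrays, 3 per gland and treatment. Per the labels, each array held RNA of a pool of 10 glands from 5 animals, although the labels also give 4 animals per sex and experiment. The labels do not say whether pools of 1 letter in different glands came from the same mice, and they name neither the array, the scanner nor the method of scaling.

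The deposited values are probe intensity on a linear scale, scaled so that each array's median lay between 0.929 and 0.952. How the authors subtracted background and scaled the arrays is not given in the sources used here. The medians were close, so the deposited scaling was kept. The value -1 occurred on each array far below all other values and was read as a code for no value (37 to 118 probes per array), although values at or below 0 had been planned to count as 0. Other values below 0 (the lowest was -0.128) were set to 0. The arrays' number limits the precision, and Spearman correlations between pools of a group ran from 0.904 to 0.953 in the lacrimal and submandibular glands and from 0.984 to 0.992 in the meibomian gland.

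Values were changed to log2(value + 0.174), where the offset is the 10th percentile of the positive values. Probes were tested if they had at least 2 values in each group and lay above the 40th percentile of their array on at least 3 of the 18 arrays. Of 10500 probes, 146 were left out for missing values and 2891 as dim, which left 7463. The annotation named 1 gene for 8983 probes, 1 probe had several and 1516 had none. Of the tested probes 6575 named 1 of 6485 genes and 888 were unnamed. A RefSeq gene table changed 0 symbols. Several probes of a gene were tested separately, and of 88 genes with more than 1 tested probe none was called in both directions in any gland. Where any probe of such a gene was called, all were called for 6 of 34 genes in the lacrimal gland. In the meibomian and submandibular glands this held for 0 of 1 and 0 of 9 genes.

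All 18 arrays were fitted in limma 3.58.1 (R 4.3.3) with a mean per group, 12 residual degrees of freedom and eBayes with a trend, and Benjamini-Hochberg adjusted p-values over all tested probes with a threshold of 0.05. The contrasts were testosterone against placebo within each gland, the differences of these between glands, a moderated F test of those differences over the 3 glands, and the placebo groups of each pair of glands. The 6 arrays of 1 gland fitted alone leave 4 residual degrees of freedom. Each of 32 gene lists, fixed before the data were examined, was counted over all probes and adjusted over the list alone. The 28 lists with at least 5 tested probes were tested on the 7306 probes without missing values with limma camera at a preset correlation of 0.01, with the correlation estimated, and with limma fry. Their p-values were adjusted over the lists within a comparison. On simulated data with known changes the same fit recovered 80% of changes of 1 in the lacrimal, 73.5% in the meibomian and 81.7% in the submandibular gland, and 23.1%, 20% and 27% of changes of 0.5. False calls made up 8.33%, 2.4% and 14.8% of all calls there, above the 5% aimed at in the lacrimal and submandibular glands. The simulation was a single draw, with variances averaged between each group's own and that of the joint fit. In the lacrimal gland it changed 65, 70 and 65 of 7306 probes by 0.5, 1 and 2. These are far fewer probes than were called in the real lacrimal data, so the rates may not carry over.

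Genes named were chosen by a rule written before the data were examined: per gland, the 12 largest rises and the 12 largest falls among called probes with 1 symbol and the replicates of the groups apart, up to 4 called members of each list or up to 2 members where none was called, up to 10 genes called the same way in all 3 glands, up to 6 called in opposite ways, the 8 largest differences between glands, and a few genes always reported where measured, some of which are not reported here. Placebo comparisons name members of lists only. Genes shown in the plot of intensities were taken from these. Values per pool of Scgb1b2 and Klk1b5 were looked at after the data were seen.

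Alternatives fixed beforehand were each gland alone, a 4-fold smaller and larger offset, no filter and a filter at the array median, quantile normalization over all arrays and within glands, scaling to a common median, other variance models, array weights, other thresholds, 1 probe per gene for the lists, replicate letter as a block, pool as a random block and leaving out each array. Added after seeing the data were -1 counted as 0, named probes only, and leaving out 88 probes above 0.8 of the maximum of a meibomian array. Residuals of pools with 1 letter did not pair: correlations within a gland ran from -0.11 to 0.14 over 9 pairs, and across glands of 1 treatment from -0.065 to 0.13 over 18 pairs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.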

Results

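RNA of the lacrimal gland, the meibomian gland and the submandibular gland of orchiectomised male BALB/c mice was measured on 1-colour arrays after 21 days with a placebo or a testosterone pellet. The lacrimal gland makes the watery part of tears, the meibomian gland is the lipid-secreting sebaceous gland of the eyelid, and the submandibular gland is a salivary gland. Per the labels each array held a pool of 10 glands from 5 animals, although the labels also give 4 animals per sex and experiment, and each of the 6 groups (3 glands, placebo or testosterone) had 3 pools, named A, B and C. The table held 10500 probes on each of 18 arrays, as intensities scaled to a median between 0.929 and 0.952, and 7463 probes were tested. Values below are mean intensities ± SD over n = 3 pools, changes are log2 testosterone minus placebo ± SE, and the number of arrays limits their precision. The annotation gave gene symbols and no coordinates. The arrays of the meibomian gland differed from the others in range: their maximum was between 134.6 and 219.1, with 27 to 42 probes within 10% of it, against 597.5 to 1042 in the lacrimal gland and 636.3 to 742.6 in the submandibular gland. Differences between this gland and the others therefore include a difference between arrays that the labels do not describe. Within the meibomian gland the range also differed between treatments. The maximum was 134.6, 139.2 and 142.9 in placebo pools A, B and C, and 219.1, 178 and 147.7 with testosterone. Changes of bright meibomian probes may therefore include this difference in range.

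The placebo groups show what each gland expressed without testosterone. Genes of lipid storage and of stratified epithelium were highest in the meibomian gland. Elovl3, a fatty acid elongase of sebaceous glands, measured 102 ± 2.87 there, against 0.432 ± 0.0668 in the lacrimal and 0.631 ± 0.00456 in the submandibular gland. Sprr1a, a cornified envelope protein, measured 111.5 ± 4.56 in the meibomian gland and 0.331 ± 0.102 in the lacrimal gland. In the lipid droplet and sebocyte list 13 of 15 probes were called highest in the meibomian gland against both others, as were 18 of 28 lipid synthesis probes, 10 of 13 cholesterol synthesis probes and 23 of 28 keratinisation probes. Eyelid tissue markers were also there: 21 of 30 skeletal muscle probes and 24 of 33 fibroblast and matrix probes were called highest in the meibomian gland, and the muscle gene Tnnc2 measured 80.1 ± 9.62. The lacrimal gland led for protein folding and secretion (41 of 62 probes) and for ribosomal proteins (30 of 58), and for the secreted antimicrobial protein Ltf, at 79.4 ± 4.29 against 8.04 ± 1.35 in the meibomian gland. Both tested granular tubule probes were called highest in the submandibular gland: the kallikrein Klk1b5 measured 687 ± 49.7 and Egf 35.2 ± 2.53. In limma at an adjusted p of 0.05, 5069 probes differed between lacrimal and meibomian placebo glands, 4973 between meibomian and submandibular, and 3284 between lacrimal and submandibular.

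In the lacrimal gland 2094 of 7463 probes passed the threshold, 991 higher and 1103 lower, and 663 of them differed at least 2-fold. This was the highest count of the 3 glands except with array weights, where the lacrimal gland had 2264 and the meibomian gland 2661. Rsph6a, a radial spoke protein of cilia, rose from 2.19 ± 0.317 to 264 ± 41.4 (6.80 ± 0.17, adjusted p = 2.19e-13). Ptch1, the hedgehog receptor, rose by 5.67 ± 0.20, the kidney enzyme Cyp4a12a by 5.59 ± 0.32, the taste cell channel Trpm5 by 5.57 ± 0.17 and Ddc, which makes dopamine and serotonin, by 5.56 ± 0.24. Mtx1, Rgs10, Stag3, Olfr140, Ly6f, Arid1a and the growth factor Mdk rose by 4.88 to 5.29. Fkbp5, an androgen-induced chaperone in several organs, rose from 1.42 ± 0.173 to 20.8 ± 3.87 (3.70 ± 0.31).

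The largest lacrimal fall was that of Pnliprp1, a pancreatic lipase-related protein, from 524 ± 39.5 to 1.03 ± 1.19 (-9.21 ± 0.95, adjusted p = 1.33e-06). Pools A and C measured 0.362 and 0.327 with testosterone, close to the 10th percentile of the lacrimal arrays (0.211 to 0.316), so the size of this fall depends on the offset. The liver glycoprotein receptor subunit Asgr1 fell from 46.3 ± 4.70 to 1.25 ± 1.51, and the alcohol dehydrogenase Adh1 from 148 ± 27.7 to 10.7 ± 2.02. Phyh, a peroxisomal enzyme of branched fatty acid breakdown, fell from 424 ± 4.02 to 38.4 ± 7.06. Tenm3, Pllp, Acy1, Snap91, Zik1, B4galt1, Retnla and Mfap3l were the other large falls, between -4.43 and -2.80. Among secretory genes, the carbonic anhydrase Car6 fell from 547 ± 24.5 to 277 ± 61.7, the scavenger protein Dmbt1 by 2.35, and the antibody transporter Pigr by 1.14 on the log2 scale. The lacrimal secretory list had 2 probes higher and 5 lower of 14, also when adjusted over the list alone, and was not called as a set with camera (adjusted p = 0.614) but was with limma fry (adjusted p = 0.0261, median -0.42).

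Genes of DNA replication and mitosis rose together in the lacrimal gland. Of 40 cell cycle probes 33 rose and 1 fell, or 34 and 1 adjusted over the list alone, with a median change of 1.32 (adjusted p = 4.14e-19, and adjusted p = 0.000664 with an estimated correlation). The proliferation marker Mki67 rose from 0.400 ± 0.0210 to 7.32 ± 1.93, the mitotic kinase Cdk1 from 0.511 ± 0.146 to 7.35 ± 2.52, and Cdc45 and Birc5 rose by 3.26 and 3.17. Lipid synthesis probes shifted up, 11 rose and 2 fell of 28 (13 and 2 adjusted over the list alone, median 0.36, adjusted p = 0.00514, but adjusted p = 0.287 with an estimated correlation). Acsbg1, which activates long-chain fatty acids, rose from 0.704 ± 0.528 to 16.4 ± 3.13, Thrsp and Scd1 rose by 1.95 and 1.37. Fasn, the fatty acid synthase, measured 3.22 ± 0.707 and 12.1 ± 8.69 on its brighter probe, and its call ended in the fit of this gland alone (adjusted p = 0.0655).

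Ribosomal protein probes fell, 37 of 58 with 2 higher (40 and 3 adjusted over the list alone, median -0.58, adjusted p = 9.90e-08). That shift was not called with an estimated correlation (adjusted p = 0.731 with an estimated correlation). Random lists matched on brightness fell by a median of -0.33, and the ribosomal median was -0.31 with quantile normalization over all arrays, so part of this fall is shared by probes of like brightness. The ribosomal median lay at percentile 0 of 10000 such lists, although the matching used only 20 brightness classes. Random lists also hold unrelated genes, so a list of genes that vary together can rank at an extreme whatever the cause. Rpl26 fell from 30.6 ± 0.714 to 9.73 ± 1.06 and Rpl37a from 370 ± 6.70 to 208 ± 32.5. Of 9 smooth muscle and myoepithelium probes 5 fell and none rose (6 fell adjusted over the list alone, median -0.67, adjusted p = 0.0169, and adjusted p = 0.305 with an estimated correlation), with the contractile proteins Myh11 and Cnn1 lower by -1.29 and -1.15. Immune genes went both ways: of 29 interferon response probes 2 rose and 7 fell (2 and 8 adjusted over the list alone, adjusted p = 0.627), and of 32 cytokine, chemokine and complement probes 5 rose and 9 fell (also adjusted over the list alone, adjusted p = 0.627, but adjusted p = 0.0161 with limma fry). B2m, the light chain of MHC class I, rose from 64.4 ± 9.85 to 318 ± 58.7, and the B cell coactivator Pou2af1 rose by 2.71. The chemokine Ccl4 fell from 107 ± 5.65 to 32.0 ± 2.69 and the acute phase protein Hp from 339 ± 37.7 to 109 ± 14.2.

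**Figure D1:**
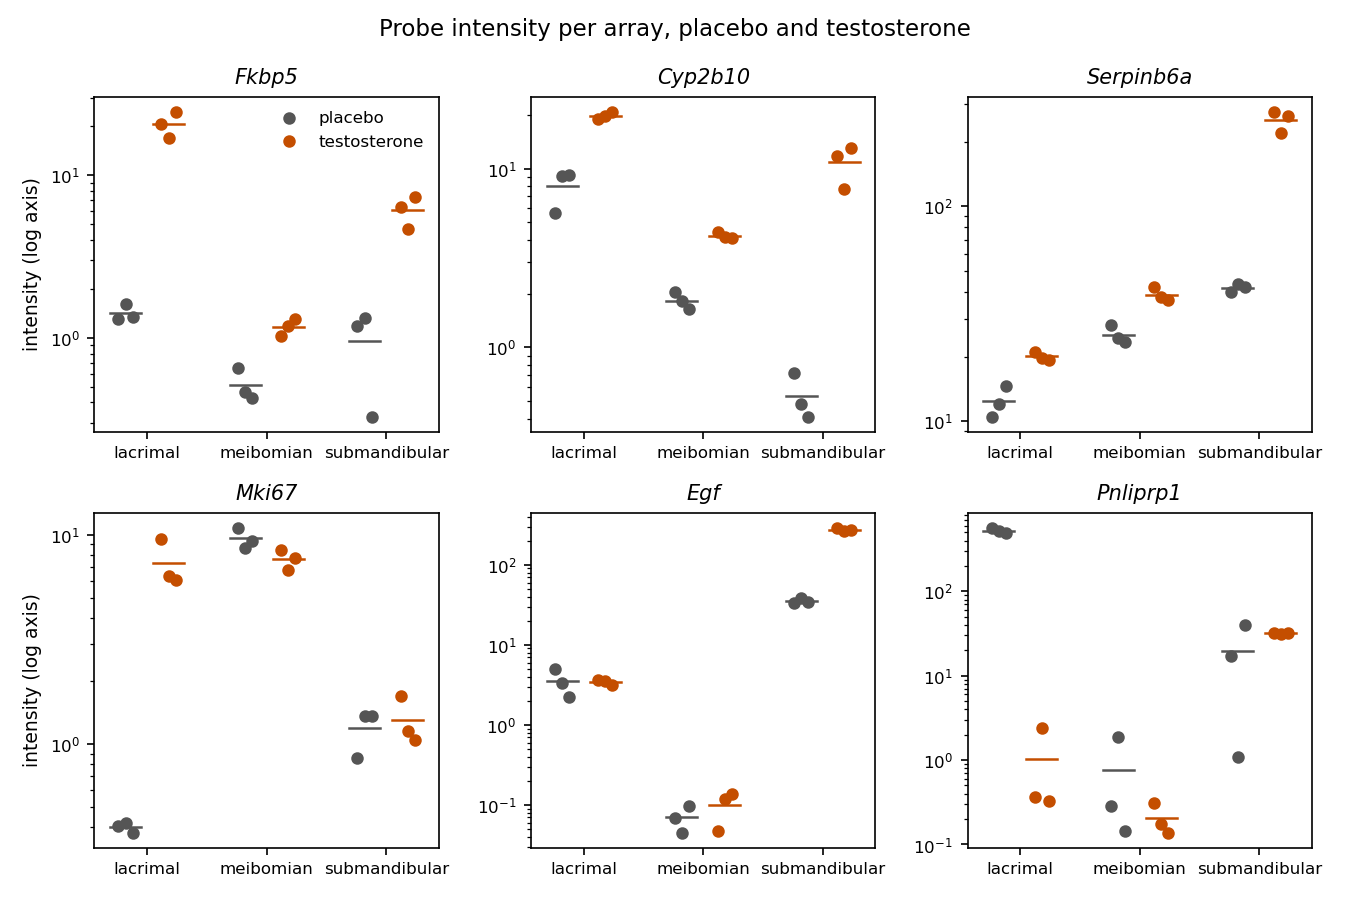
Intensity on a log axis of 6 probes in each of the 18 arrays, with placebo pools in grey, testosterone pools in orange and lines at the group means (n = 3 pools). Egf separated the groups in the submandibular gland, at 35.2 and 273, and Mki67 in the lacrimal gland, at 0.400 and 7.32.

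The meibomian gland had few calls in the joint fit of all arrays. Of 7463 probes 44 passed, 35 higher and 9 lower. That fit pools the residual variance of each probe over the glands. The median within-group SD on the log2 scale was 0.135 in the meibomian gland, against 0.219 in the lacrimal and 0.219 in the submandibular gland. Meibomian standard errors therefore include the larger spread of the other glands, and the low count alone does not show a weak response. Calls of at least 2-fold were also few, at 11, against 663 in the lacrimal and 298 in the submandibular gland. Each gland fitted alone gave 246 calls in the meibomian, 1741 in the lacrimal and 409 in the submandibular gland. Pooling of the variance therefore does not account for all of the lower count. Nmb, the bombesin-like peptide neuromedin B, rose from 4.15 ± 0.161 to 13.3 ± 3.49 (1.60 ± 0.21, adjusted p = 0.0101). Ttpa, the vitamin E transfer protein, rose by 1.49 ± 0.26, Cyp2b10 by 1.13 ± 0.21, Hp by 1.01 ± 0.19 and the ceramide synthase Cers4 by 0.87 ± 0.16. Epyc, Calcr, Acsm3, Dpf1, Rabep2, H4c9 and Entpd1 rose by 0.82 to 0.99. Sprr2a1, a cornified envelope protein, fell from 26.6 ± 11.7 to 6.73 ± 0.529 (-1.88 ± 0.28), Cxcl15 fell by 1.81 and the adipokine Retn by 1.16. Cd74, the MHC class II chaperone, fell from 16.2 ± 1.32 to 8.79 ± 0.925. Ccnt2, Srsf11 and Pef1 fell by 1.23, 1.21 and 0.87. Pef1 had the no-value code on 1 array and would read as a rise of 1.40 (adjusted p = 0.627) if that code were counted as 0. The lipid enzymes Scd1 (27.7 ± 0.718 and 33.8 ± 1.04) and Fasn (21.0 ± 1.81 and 22.0 ± 3.95), and Fkbp5 (0.514 ± 0.120 and 1.17 ± 0.135, adjusted p = 0.179), did not pass. The Fkbp5 pools did not overlap, at 0.426 to 0.651 with placebo and 1.03 to 1.3 with testosterone. The missing call therefore does not show that Fkbp5 was unchanged.

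This count depended on the model and on single arrays. The 6 meibomian arrays fitted alone gave 246 probes, 181 higher and 65 lower, with 41 of the 44 among them, and weighting arrays by quality in limma gave 2661. Limma called 0 probes at an adjusted p of 0.01, where 1058 had an unadjusted p below 0.05. Without placebo pool A or testosterone pool B limma called 0, without placebo pools B and C 2 and 4, without testosterone pool A 3, without testosterone pool C 170, and without submandibular placebo pool A 85.

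Gene lists shifted by small amounts in the meibomian gland, 6 up and 10 down of 28 tested, and none was called with an estimated correlation. Keratinisation probes shifted down (median -0.34, adjusted p = 2.70e-07, and adjusted p = 0.0519 with an estimated correlation), where 1 of 28 fell over all probes and 5 fell and 1 rose adjusted over the list alone. Interferon response probes shifted down by a median of -0.27 (adjusted p = 4.71e-05, and adjusted p = 0.218 with an estimated correlation), with 0 of 29 probes called, also adjusted over the list alone. Macrophage and MHC class II probes shifted down by -0.14 (adjusted p = 0.000825, and adjusted p = 0.218 with an estimated correlation), where Cd74 fell and 4 of 26 fell adjusted over the list alone. The interferon and macrophage lists were not called with limma fry (adjusted p = 0.247 and 0.161). Fry did call the keratinisation list and the steroid metabolism list (adjusted p = 0.0252 for each). Steroid metabolism and receptor probes shifted up by 0.24 (adjusted p = 0.00578, and adjusted p = 0.218 with an estimated correlation), with 0 of 24 called and 3 higher adjusted over the list alone. Its members Hsd11b1, which regenerates active glucocorticoid, measured 0.855 ± 0.198 and 1.78 ± 0.312, and Akr1c18 7.54 ± 0.227 and 11.4 ± 0.720.

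Ribosomal (0.34), oxidative phosphorylation (0.27), lipid synthesis (0.27), cholesterol synthesis (0.25) and fatty acid oxidation (0.23) lists also shifted up in the meibomian gland, at adjusted p = 4.55e-10, 2.81e-05, 0.0213, 0.0205 and 0.00744. None was called with an estimated correlation, at adjusted p = 0.218, 0.221, 0.218, 0.218 and 0.226 with an estimated correlation. All were called with limma fry, at adjusted p = 0.0252, 0.0314, 0.0252, 0.0252 and 0.0315. Over all probes 1, 1, 0, 0 and 0 members rose and none fell, and adjusted over the list alone 1, 1, 0, 4 and 0 rose. These 5 camera calls ended with quantile normalization over all 18 arrays, where the ribosomal median was 0.01 and its set test turned down (adjusted p = 0.999), and with quantile normalization within the gland. The lipid synthesis call also ended without placebo pool A (adjusted p = 0.0670) or testosterone pool C (adjusted p = 0.0525). In this gland the median change was also highest among the brightest probes, at 0.14 in the ninth and 0.27 in the tenth decile, against 0.09 in the first, -0.02 in the third and 0.08 in the eighth. The 99th percentile of intensity was 97.67 to 100.5 on its placebo arrays and 105.9 to 148.1 on its testosterone arrays.

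In the submandibular gland 1029 probes passed, 637 higher and 392 lower, 298 of them at least 2-fold. Fitted alone, the 6 submandibular arrays gave 409, 297 higher and 112 lower, of which 396 were among the 1029. The joint fit includes the smaller spread of the meibomian arrays, so submandibular and lacrimal standard errors may be too small there. The fit alone also has fewer residual degrees of freedom, so the reason for its lower count cannot be told apart. Ptgds, the prostaglandin D synthase, rose from 0.475 ± 0.0688 to 40.9 ± 8.03 (5.97 ± 0.18, adjusted p = 4.31e-12). Egf, epidermal growth factor, rose from 35.2 ± 2.53 to 273 ± 15.2 (2.95 ± 0.20), the salivary peptide Smr2 from 4.85 ± 0.313 to 83.3 ± 15.0, and the estrogen sulfotransferase Sult1e1 from 6.40 ± 0.426 to 109 ± 31.1. The bicarbonate cotransporter Slc4a4 rose by 3.82 ± 0.22, Mdk by 3.56 ± 0.37 and Fkbp5 by 2.61 ± 0.31. St6galnac2, Cyp2b10, Klrg2, Tmem37, Ttr and Sgca rose by 2.87 to 4.49, and the growth factors Tgfb2 and Vegfa by 2.37 and 2.13. The sialyltransferase St3gal1 fell from 11.4 ± 1.90 to 1.73 ± 0.545 (-2.63 ± 0.25), Tmigd1 by 2.56, the surface antigen Psca by 2.14 and Mucl1 by 2.07. The digestive enzyme gene Ctrb1, with Hilpda, Slc37a2, Rap1gap and Foxo1, fell by 1.68 to 1.91. Clps, Acot1 and Ncam2 also passed (-1.94, -1.79 and -1.69), and each lost its call in the fit of this gland alone and without 1 or more of the submandibular placebo pools. Klk1b5 measured 687 ± 49.7 and 509 ± 54.4, and was not called, also not in the fit of this gland alone. Its pools did not overlap, at 647 to 743 with placebo and 462 to 568 with testosterone. The missing call therefore does not show that Klk1b5 was unchanged.

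Connective tissue and contractile genes rose together in the submandibular gland. Of 33 fibroblast and matrix probes 16 rose and 1 fell (21 and 2 adjusted over the list alone, median 0.62, adjusted p = 5.49e-06, and adjusted p = 0.245 with an estimated correlation), among them the protease inhibitor Timp3 (4.10 ± 0.164 to 11.9 ± 1.35) and Mgp (10.1 ± 0.646 to 24.8 ± 2.37). Of 9 smooth muscle and myoepithelium probes 6 rose (6 rose and 1 fell adjusted over the list alone, median 0.92, adjusted p = 0.00150, and adjusted p = 0.245 with an estimated correlation), with Tagln and Cnn1 higher by 1.65 and 1.13. Protein folding and secretion probes rose, 19 of 62 with none lower (19 and 2 adjusted over the list alone, median 0.22, adjusted p = 0.000704, and adjusted p = 0.373 with an estimated correlation), with Ero1a and Pdia4 higher by 1.78 and 0.90. Stress and immediate early genes shifted up, 4 of 24 (4 adjusted over the list alone, median 0.45, adjusted p = 0.00147, and adjusted p = 0.349 with an estimated correlation), with Gadd45a from 7.62 ± 0.120 to 46.9 ± 5.88. Without testosterone pool B this median was 0.20 and the call ended (adjusted p = 0.104). Macrophage and MHC class II probes shifted up, 5 of 26 (6 adjusted over the list alone, median 0.24, adjusted p = 0.0105, and adjusted p = 0.349 with an estimated correlation), with the receptor Cd14 from 5.38 ± 0.192 to 15.3 ± 2.83, and the list lost its call without placebo pool B (adjusted p = 0.0563).

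Markers of fat and striated muscle shifted down in the submandibular gland. Of 14 adipose probes 3 fell (5 adjusted over the list alone, median -0.57, adjusted p = 0.00830, and adjusted p = 0.322 with an estimated correlation), and of 30 skeletal muscle probes 6 fell and 1 rose (also adjusted over the list alone, median -0.33, adjusted p = 0.00712, and adjusted p = 0.414 with an estimated correlation). The muscle list lost its call without placebo pool A (adjusted p = 0.135) and with limma fry (adjusted p = 0.0577). The adipose list kept its call with limma fry (adjusted p = 0.00355). The fit of this gland alone called none of these probes. Retn measured 7.62 ± 1.92 and 4.04 ± 0.580, the muscle calcium pump Atp2a1 3.56 ± 2.21 and 0.883 ± 0.335, and Cox8b 22.9 ± 9.59 and 7.23 ± 3.10. The mean log2 level of the muscle list was 0.37, -0.13 and 0.00 in placebo pools A, B and C, and -0.17, -0.31 and -0.40 with testosterone. The fatty acid binding protein Fabp5 fell from 24.6 ± 1.72 to 7.87 ± 0.179. The lipogenic gene Scd1 measured 20.2 ± 2.95 and 8.38 ± 3.77 (-1.33 ± 0.23, adjusted p = 0.000817). Of the 28 lipid synthesis probes, to which Scd1 belongs, 4 fell in the joint fit and 0 in the fit of this gland alone.

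**Figure D2:**
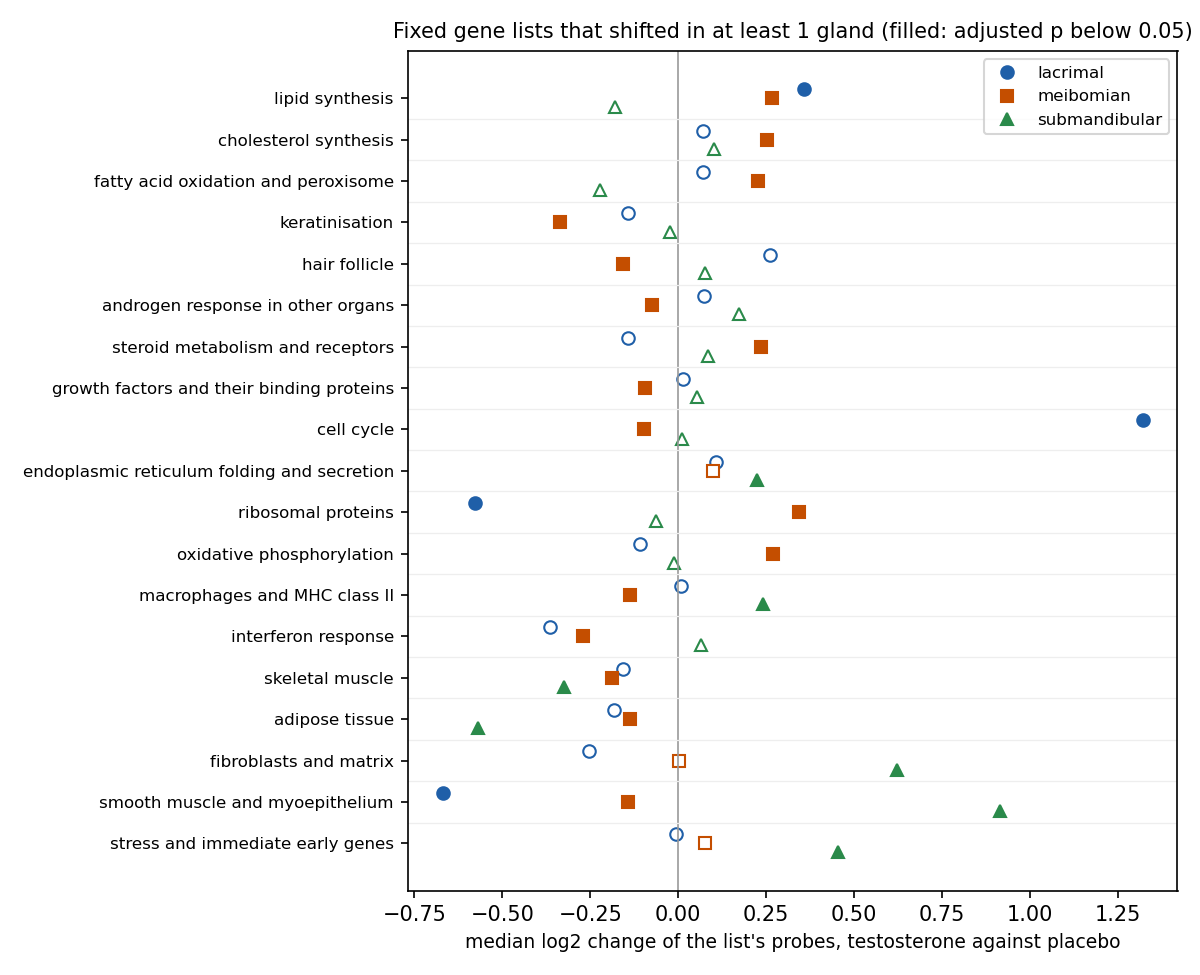
Median log2 change of each of 19 gene lists that shifted in at least 1 gland, with the gland shown by shape and colour and filled symbols at an adjusted p below 0.05 (limma camera). The cell cycle list stands at 1.32 in the lacrimal gland, with an adjusted p of 0.000664 with an estimated correlation, and no other list kept its call with an estimated correlation.

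Across glands, 417 probes were called in both the lacrimal and the submandibular gland, 245 in the same and 172 in opposite directions. Both were higher for 142 probes, where independent calls would give 84.6, and both lower for 103, where they would give 57.9. Opposite pairs numbered 64 and 108, against 52.1 and 94.1. The lacrimal and meibomian glands shared 19 calls, 10 in the same direction, and the meibomian and submandibular glands shared 10, 7 of them in the same direction. Of the 19, 7 were higher and 3 lower in both, against 4.65 and 1.33 for independent calls. The other 9 were lower in the lacrimal and higher in the meibomian gland, against 5.17. Of the 10, 5 were higher and 2 lower in both, against 2.99 and 0.473. The other 3 were higher in the meibomian and lower in the submandibular gland, against 1.84. The meibomian overlaps rest on 44 calls and moved with single arrays: they were 0 or 1 without any of 5 of the 6 meibomian arrays, and 31 and 34 with the lacrimal and 24 and 11 with the submandibular gland without meibomian testosterone pool C. Across all probes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.103 and a Spearman correlation of 0.0549 between lacrimal and submandibular glands. These were 0.086 and 0.0947 between lacrimal and meibomian glands, and 0.0283 and 0.022 between meibomian and submandibular glands.

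Of 7 probes called in all 3 glands, 4 had the same direction, and 3 of these are named. The meibomian calls of all 3 ended without any 1 of the 6 meibomian arrays except testosterone pool C (adjusted p from 0.0712 to 0.201), and that of Serpinb6a also with quantile normalization over all arrays (adjusted p = 0.104) or within glands (adjusted p = 0.147). Cyp2b10, an inducible drug-metabolising cytochrome, rose by 1.32 ± 0.21 in the lacrimal, 1.13 ± 0.21 in the meibomian and 3.94 ± 0.21 in the submandibular gland. Serpinb6a, a protease inhibitor, rose by 0.70 ± 0.13, 0.62 ± 0.13 and 2.58 ± 0.13. Retn fell by 0.73, 1.16 and 0.87, and its lacrimal call ended without lacrimal placebo pool A (adjusted p = 0.0911) or testosterone pool C (0.0664). Its submandibular call ended without submandibular placebo pool C (adjusted p = 0.0667) or testosterone pool A (0.0569), and in the fit of that gland alone.

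Whether testosterone acted differently among the glands was tested directly, and 2066 probes differed among the 3. Between lacrimal and submandibular glands 1794 probes differed in their change, between lacrimal and meibomian 1315, and between meibomian and submandibular 552. The last became 360 without meibomian placebo pool A. Pnliprp1 differed most, by -10.96 ± 1.34 between lacrimal and submandibular glands (adjusted p = 1.57e-05), a size that also depends on the offset. It measured 16.9, 1.09 and 40.4 in submandibular placebo pools A, B and C. Rsph6a, Ptch1, Ddc and Trpm5 differed by 7.29, 6.15, 5.87 and 5.68 between the same glands, Cyp4a12a by 5.81 between lacrimal and meibomian glands, and Ptgds by -6.01 between meibomian and submandibular glands. Some genes went opposite ways. The transcription factor Sox11 rose from 1.62 ± 0.168 to 38.6 ± 24.2 in the lacrimal gland and fell from 4.93 ± 0.228 to 1.72 ± 0.463 in the submandibular gland, a difference of 5.73 ± 0.40. Twist2 and Pxt1 also rose in the lacrimal and fell in the submandibular gland, with differences of 4.28 and 4.42. Arid1a, Mink1 and Ftsj1 differed by 5.38, 4.54 and 4.34, and their submandibular falls of 0.50, 0.52 and 0.68 held less firmly: those of Mink1 and Ftsj1 ended in the fit of this gland alone, and that of Arid1a ended without placebo pool B or C or testosterone pool A or B.

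The cell cycle list differed in its change between the lacrimal gland and each of the others. Against the meibomian gland 29 of 40 probes differed and the median difference was 1.46 (adjusted p = 2.08e-22, and adjusted p = 0.000302 with an estimated correlation), and against the submandibular gland 31 differed and it was 1.37 (adjusted p = 8.17e-17, and adjusted p = 0.00123 with an estimated correlation). In the placebo groups 28 of the 40 probes were called highest in the meibomian gland, where Mki67 measured 9.62 ± 1.09. Smooth muscle and myoepithelium probes differed between lacrimal and submandibular glands, 6 of 9, with a median of -1.50 (adjusted p = 0.000579, and adjusted p = 0.117 with an estimated correlation). The median difference over all probes was -0.11 between lacrimal and meibomian glands, so list differences there stand relative to that shift.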

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

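The tests of fat and muscle markers over the placebo pools, of dilution by other cells and of lymphocyte markers were chosen only after the results they measure were seen.

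The change with testosterone differed between glands by a direct test for 1315 probes between lacrimal and meibomian, 1794 between lacrimal and submandibular and 552 between meibomian and submandibular glands, and for 2066 probes over the 3. Of 100 splits of the arrays within glands, the real 1 included, 2 gave at least 1315, 1 gave at least 1794, 2 gave at least 552 and 1 gave at least 2066, so chance can be excluded only for no effect of testosterone in either gland. The splits do not test whether the effects were equal, and the differences rest on the limma tests. The highest other splits gave 1533, 1065, 598 and 1736. Those of 1533 and 598 had the real groups in both glands with the treatments of 1 gland exchanged, and those of 1065 and 1736 kept the real groups of the lacrimal gland and of the lacrimal and submandibular glands.

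For the counts within a gland, 10 splits of 6 arrays are too few for a share under 0.05. The real split gave 2094 calls in the lacrimal, 44 in the meibomian and 1029 in the submandibular gland, and the highest other split 2, 1 and 29. For placebo glands the real splits gave 5069 (lacrimal and meibomian), 3284 (lacrimal and submandibular) and 4973 (meibomian and submandibular), and the highest others 0, 1 and 0. In each of these 6 comparisons only 1 split, the real 1, gave as many. Every other split mixed arrays of both treatments, or of both placebo glands, in each group. Where these differ, mixing widens the spread within groups. Few calls in those splits were therefore to be foreseen, and no conclusion on the within-gland counts or the placebo differences is drawn from them.

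Genes whose change differed between lacrimal and submandibular glands by the same test were Pnliprp1 (-10.96), Rsph6a (7.29), Ptch1 (6.15), Ddc (5.87), Sox11 (5.73), Trpm5 (5.68), Arid1a (5.38), Mink1 (4.54), Pxt1 (4.42), Ftsj1 (4.34) and Twist2 (4.28). Cyp4a12a differed between lacrimal and meibomian glands (5.81) and Ptgds between meibomian and submandibular glands (-6.01). The cell cycle list differed by a median of 1.46 between lacrimal and meibomian and of 1.37 between lacrimal and submandibular glands.

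The lacrimal rise of the cell cycle list (median 1.32) is the first pattern weighed. With a 4-fold larger offset the median was 1.003 (adjusted p = 3.40e-19), and with quantile normalization within each gland 1.27 (adjusted p = 4.27e-19), which argues against the offset and against scaling between arrays as the cause. Over 19 probes of T, B and plasma cell markers the median change was -0.072 with an upper quartile of 0.27, so an explanation by more lymphocytes cannot be told apart: their markers moved both ways, Pou2af1 and Gzmb up and Cd5 down. A candidate explanation is that testosterone raised the number of dividing cells in the gland, and which cells these might be was not measured.

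The meibomian rise of 6 lists is the second. Among 10000 random lists matched on brightness, the median of the oxidative phosphorylation list lay at percentile 52.45, cholesterol synthesis at 83.04, fatty acid oxidation at 96.76 and lipid synthesis at 96.99, which leaves probe brightness as a candidate explanation for these 4. The ribosomal list lay at 98.9, past the bound set before the test for ruling brightness out, but after seeing the result this was not relied on: its median of 0.34 stood beside 0.30 in the matched lists and became 0.00 with quantile normalization within the gland, and the matching used only 20 brightness classes, so brightness cannot be told apart there. The steroid metabolism list lay at 99.75, against a matched median of 0.07. Random lists hold unrelated genes, so genes that vary together can rank high whatever the cause, and the percentile alone does not decide. The list kept its median and its camera call with that normalization (0.22, adjusted p = 0.00289), which argues against brightness as its whole cause. An effect of testosterone stays open for all 6, none of which was called with an estimated correlation. Limma fry called all 6 (adjusted p from 0.0252 to 0.0315). It does not set a list against other probes, so it cannot tell brightness apart.

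The submandibular fall of fat and striated muscle markers is the third. The spread of the list over the 3 placebo pools lay at percentile 95.28 of brightness-matched lists for adipose and at percentile 100 for skeletal muscle probes. Random lists hold unrelated genes, so a list of genes that vary together would rank high whatever the cause. The test therefore cannot decide whether differing amounts of other tissue in the placebo pools account for part of both falls. The adipose SD was 0.201 over placebo and 0.15 over testosterone pools, and the muscle SD 0.262 and 0.113. Mean log2 levels of the adipose list were 2.35, 2.27 and 2.65 in placebo pools A, B and C, and 1.76, 2.02 and 2.01 with testosterone. Dilution by more epithelium would lower connective tissue markers as well, and the fibroblast and matrix list had a median change of 0.62. That argues against a like dilution of all other cell types. The test used that list alone, and the endothelium list fell, so dilution of some cell types is not excluded. Dilution by more connective tissue cannot be told apart, since the endothelium list had a median of -0.34 and the macrophage list of 0.24, and neither was called with an estimated correlation, nor the former with the preset 1 (adjusted p = 0.0738). A change in the tissue with testosterone also stays open.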

How the results depend on the processing

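Alternatives with -1 counted as 0, with named probes only and without probes near the meibomian ceiling were chosen after seeing the data. The lacrimal, submandibular, gland-difference and placebo counts stayed within 1.5 times of the reported ones except as given here, and the meibomian count did not. Causes were not tested except where a threshold or fewer arrays by construction change a count. At 1% the counts were 1328 (lacrimal), 0 (meibomian, limma, where 1058 had an unadjusted p below 0.05), 507 (submandibular), 733 (lacrimal against meibomian), 1003 (lacrimal against submandibular), 242 (meibomian against submandibular) and 1131 (among 3 glands). With at least 2-fold they were 663, 11, 298, 718, 953, 311 and 1230, and 2936, 1166 and 2575 for the placebo pairs lacrimal and meibomian, lacrimal and submandibular, and meibomian and submandibular. At 10% the meibomian count was 129 and the meibomian against submandibular count 915. Each gland alone gave 246 meibomian and 409 submandibular calls. A 4-fold larger offset gave 77 meibomian calls, array weights 2661 meibomian, 2322 lacrimal against meibomian and 1258 meibomian against submandibular calls, and quantile normalization over all arrays 28 meibomian calls, 18 higher and 10 lower. With the replicate block the counts were 2105 (lacrimal), 39 (meibomian) and 1053 (submandibular).

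Lacrimal and submandibular calls shared in the same and in opposite directions were 103 and 56 with each gland alone, 117 and 64 at 1%, 374 and 277 at 10%, and 59 and 14 with at least 2-fold. Lacrimal and meibomian ones were 52 and 28 alone, 17 and 16 with the larger offset, 0 and 0 at 1%, 36 and 20 at 10%, and 1 and 1 with 2-fold, with 5 in the same direction for quantile normalization over all arrays and 5 opposite for a common median. Meibomian and submandibular ones were 14 and 6 alone, 14 and 5 with the larger offset, 0 and 0 at 1%, 24 and 20 at 10%, and 3 and 1 with 2-fold. Quantile normalization within glands turned their balance to 4 and 7, and over all arrays 7 were opposite.

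Shifted lists numbered 1 (lacrimal), 0 (meibomian) and 0 (submandibular) with an estimated correlation, and 12, 8 and 13 with fry, which asks another question. Quantile normalization within glands gave 9 (meibomian, 1 up and 8 down) and 11 (submandibular) lists, and over all arrays 11 submandibular lists. Reversed were the meibomian ribosomal list with quantile normalization over all arrays (median 0.0115, adjusted p = 0.999), Pef1 in the meibomian gland with -1 counted as 0 (1.40, adjusted p = 0.627), and the direction of the set test for the salivary secretory list in the submandibular gland, up with fry (adjusted p = 0.0175) and down but not called with camera (adjusted p = 0.558), at the same median of -0.24.

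Leaving out 1 array gave 0 (without meibomian placebo A) to 170 (without meibomian testosterone C) meibomian calls and 360 (without meibomian placebo A) to 704 meibomian against submandibular calls. Shared calls ranged from 0 to 31 (same) and 0 to 34 (opposite) for lacrimal and meibomian, and from 0 to 24 and 0 to 11 for meibomian and submandibular glands. Lacrimal counts ranged from 1680 to 2215 and submandibular from 738 to 1141. Of 127 named lacrimal calls 22, of 22 meibomian 22 and of 101 submandibular 27 were lost without at least 1 array, and with each gland alone 7, 1 and 41. The low ends limit dim probes: the 10th percentile of intensity was 0.0514 to 0.0741 on meibomian and 0.211 to 0.316 on other arrays.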

Other observations

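Fluid transport and growth factor genes changed in both directions. In the lacrimal gland 8 of 29 ion and water transport probes fell and 3 rose, 9 and 3 adjusted over the list alone (adjusted p = 0.105 for the list), with the potassium channel Kcnma1 from 16.1 ± 1.53 to 4.78 ± 0.929 on its brighter probe and the sodium pump subunit Atp1b3 lower by -1.35. In the submandibular gland 5 rose and 3 fell, 7 and 6 adjusted over the list alone (adjusted p = 0.488). Of 33 growth factor probes 8 rose and 7 fell in the lacrimal gland (8 and 7 adjusted over the list alone, adjusted p = 0.672), with Bmp6 from 0.312 ± 0.0744 to 4.55 ± 0.789, the activin antagonist Fst higher by 3.21 and the stem cell factor Kitl lower by -1.32. In the submandibular gland 9 rose and 3 fell (10 and 4 adjusted over the list alone, adjusted p = 0.0748). Steroid enzymes also changed: in the lacrimal gland 4 probes rose and 4 fell of 24 (4 and 5 adjusted over the list alone, adjusted p = 0.803), and in the submandibular gland 4 rose and 1 fell (also adjusted over the list alone, adjusted p = 0.148), among them Hsd17b3, which makes testosterone, from 0.354 ± 0.0709 to 2.58 ± 1.12.

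Androgen response genes known from other organs moved both ways: 4 up and 4 down of 16 in the lacrimal gland (also adjusted over the list alone, adjusted p = 0.670) and 3 up and 1 down in the submandibular gland (4 and 1 adjusted over the list alone, adjusted p = 0.118). Sgk1 rose from 6.53 ± 0.361 to 23.5 ± 6.57 there. T cell (10 probes) and B and plasma cell (9 probes) lists were not called with camera in any gland, at adjusted p = 0.803, 0.983 and 0.558 and adjusted p = 0.682, 0.858 and 0.249 in lacrimal, meibomian and submandibular glands. The B and plasma cell list was called in the lacrimal gland with limma fry (adjusted p = 0.0490) and in the submandibular gland without placebo pool C (median -0.37, adjusted p = 0.0396). With fry the transport, growth factor and androgen response lists were also called in both of these glands, and the steroid list in the submandibular gland.

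Some secretory genes read far higher in single pools than in the other pools of the same gland. Scgb1b2 measured 98.3 in meibomian placebo pool B, 3.82 and 3.40 in placebo pools A and C and 4.83 to 9.35 in the testosterone pools, against 1040, 984 and 977 in the lacrimal placebo pools A, B and C and 439 to 467 in the submandibular placebo pools. Klk1b5 measured 14.7 in lacrimal placebo pool A and 10.7 in lacrimal testosterone pool C, and 0.316 to 0.648 in the other 4 lacrimal pools. In the lacrimal placebo pools Amy1 (42.0 ± 67.2) and Chia1 (29.1 ± 48.0) had an SD above their mean, against 257 ± 23.9 and 249 ± 40.2 in the submandibular placebo pools.

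In the meibomian gland small downward shifts were also called for the lists hair follicle (-0.16, adjusted p = 0.0299 and 0.293 with an estimated correlation), growth factor (-0.09, adjusted p = 0.00698 and 0.218 with an estimated correlation), androgen response (-0.08, adjusted p = 0.0299 and 0.218 with an estimated correlation), cell cycle (-0.10, adjusted p = 0.00866 and 0.218 with an estimated correlation). The same held for skeletal muscle (-0.19, adjusted p = 0.0213 and 0.384 with an estimated correlation), adipose tissue (-0.14, adjusted p = 0.0419 and 0.221 with an estimated correlation) and smooth muscle and myoepithelium (-0.14, adjusted p = 0.0299 and 0.221 with an estimated correlation). None of these 7 was called with an estimated correlation, and with limma fry only the androgen response list was (adjusted p = 0.0252). Single arrays carried several of the camera calls. Without testosterone pool C the hair follicle and smooth muscle medians were 0.00 and 0.03 (adjusted p = 0.564 and 0.251), so their direction was gone, and the adipose median was -0.05 (adjusted p = 0.161). The hair follicle call also ended without placebo pool A or C and in the fit of the gland alone, and the skeletal muscle call without placebo pool A or C or testosterone pool A or B. The adipose call of camera also ended without placebo pool B or C and in the fit of the gland alone (adjusted p = 0.0907). It ended too with the replicate block (adjusted p = 0.0517), the 4-fold larger offset (0.067) and quantile normalization over all arrays (0.0691) or within glands (0.0593). The ornithine decarboxylase gene Odc1 rose in the lacrimal gland from 4.68 ± 0.287 to 7.95 ± 0.477 (log2 change 0.74, adjusted p = 0.00331) and was not called in the meibomian (-0.05) or submandibular gland (0.13).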
